A study of Mus musculus with 6 samples.

How the data were processed

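RNA was measured in keratinocytes sorted from the back-skin epidermis of 6 mice. Per the labels' protocols, RNA was purified with a micro-scale column kit, amplified as full-length cDNA with a single-cell kit and converted to libraries with a transposase kit. Such libraries are amplified by PCR, and the labels name neither molecular identifiers nor strand. The cell type label is keratinocyte, and the series text names the sorted cells by an abbreviation that is not expanded there. The sample descriptions and count columns carry the prefix IFE, so the exact sorted population is not settled by the labels.

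The authors deposited raw read counts per gene with Ensembl identifiers, symbols and gene lengths. Per the submitters' processing notes, the tools were fastp 0.12.4, HISAT2 2.2.1 and featureCounts 2.0.1 with genome build mm10. The annotation release and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes cannot be separated. Counting can also split reads between near-identical genes such as the Lce1 family, haemoglobins, stefins and ribosomal proteins with processed pseudogenes. The table also held 6 columns of per-sample values that match no sample of the series; they were not used.

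The 32190 deposited rows held 140 Ensembl identifiers on several rows, with identical counts on each, and 231 repeats were dropped to leave 31959 genes. Of these identifiers 31912 (99.9%) were found in GENCODE M21, an annotation of mm10, which gave coordinates, biotype and transcript sequence. The deposited gene length equalled the M21 exon union for 98.8% of the matched identifiers. GC content was taken from the longest transcript of a gene.

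Total counts per library ranged from 7836022 to 13658670, at which 3 counts, taken as the floor, are 0.204 to 0.454 CPM. Samples were grouped by genotype as labelled: control, the receptor allele alone, and suppressed, the allele with Dbh Cre, with 3 mice in each group and CNO in both. The labels name separate mice. Mouse numbers are not shared between the groups, so nothing pairs the samples. The only comparison is suppressed against control.

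Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, after preparation in Python 3.11.15 with pandas 2.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), scaled by TMM and tested with a robust quasi-likelihood F test, Benjamini-Hochberg adjusted with a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of F. CPM values are TMM-normalised. The floor is 3 counts per library; folds against a group at 0 use the mean floor of that group. A total of 25 pathway lists, 11 cell-type marker lists and 2 check lists (mitochondrially encoded and sex-linked genes) were fixed before the data were examined, and the 30 pathway and marker lists with at least 5 tested genes were tested with camera (preset correlation 0.01, two-sided), camera with an estimated correlation, and fry. List levels per library are means of log2(CPM + 1) over the detected members.

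Genes named in the text follow a rule fixed before the data were examined. With no gene past the threshold, it takes the 4 genes of smallest p in each direction with non-overlapping groups and a mean of at least 5 CPM, leaving out Gm and Rik gene models and pseudogenes. It adds up to 2 genes of smallest p per pathway list, every chemokine at an unadjusted p under 0.05 (there were 0), the 3 most abundant chemokines, Adrb1, Dbh, Chrm4, Krt5 and Krt14, and the 2 most abundant members of each marker list. Some results that the rule takes are not reported here. Other genes are stated as named after their values were seen, or are given to describe single libraries or list members in the same way.

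The alternatives fixed in advance were other normalisations (DESeq2 size factors, upper quartile), no low-count filter or a mean of at least 5 CPM, DESeq2, limma voom without and with sample quality weights, an adjusted p of 0.1, a test against a fold change of 1.5, leaving out each mouse, leaving out mitochondrially encoded or Y-linked and Xist genes, and the other set tests. Chosen after seeing the data were summing controls 22 and 23 into 1 sample, leaving out suppressed mice 18 and 68 together, and removing each library's smooth trend on GC content and gene length (loess, span 0.5) through offsets.

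The fits were tested on simulated data: negative binomial counts for the 12090 tested genes with the real means, library sizes and spread, and 200 genes changed by known folds. With the real spread the quasi-likelihood test recovered 0%, 4%, 18% and 52% of genes changed 2-, 4-, 8- and 16-fold, with 0 false calls. DESeq2 recovered 4%, 32%, 72% and 94%, with 62 false calls among 164. With a coefficient of variation of 0.2 the quasi-likelihood test recovered 76% of genes changed 2-fold and 100% of the others, with 13 false calls among 216. In camera, a raised list of simulated genes had a p of 8.606e-10 and an unchanged list 0.7541 with the real spread. Simulated genes vary independently, unlike real ones.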

Results

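Messenger RNA was sequenced from keratinocytes sorted out of the back-skin epidermis of 6 mice. All mice received clozapine N-oxide (CNO), a ligand that activates an engineered inhibitory receptor (Gi-DREADD). In the 3 suppressed mice, numbered 18, 68 and 69, a Cre recombinase driven from the Dbh locus switched the receptor on in noradrenergic cells, to lower sympathetic nerve activity under CNO. The 3 control mice, numbered 15, 22 and 23, carried the receptor allele without Cre. Total counts on genes were 9364821, 13658670 and 13068926 in controls 15, 22 and 23, and 7836022, 8661942 and 11063056 in suppressed mice 18, 68 and 69. A value of 3 counts, taken as the floor, corresponded to 0.204 to 0.454 CPM (TMM-normalised counts at a common library size) across the libraries. The labels name no molecular identifiers, and without them floors cover counting error only. Each mean below is over 3 mice and is given with its SD. Controls 22 and 23 were nearly identical, with a coefficient of variation of 0.04996 between them against 0.284 for the next closest pair. They may be 1 RNA sample, so the control SDs may understate the spread between mice.

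The study asked which molecule of the epidermis draws in CD8+ T cells when sympathetic activity is lowered, so chemokine genes were examined first. None of the 14 tested chemokine genes passed the threshold between the groups, either adjusted over all genes or over the list alone. The smallest adjusted p over the list alone was 0.627 (edgeR quasi-likelihood test). The list held 33 chemokine genes, of which 26 were detected, and those not tested are left undecided. In simulated counts with the observed spread, this test recovered 0% of genes changed 2-fold and 18% of genes changed 8-fold. A change of such a size could therefore have been missed. The most abundant was Ccl27a, a keratinocyte chemokine that attracts skin-homing T cells, at 848 ± 42.2 CPM in controls and 937 ± 260 CPM in suppressed mice. Cxcl14 stood at 440 ± 7.90 and 581 ± 217 CPM. Cxcl16, the ligand of CXCR6, a chemokine receptor found on T cells, stood at 289 ± 22.7 and 257 ± 49.0 CPM. The log2 fold changes (suppressed minus control) with their standard errors were 0.14 ± 0.34 for Ccl27a, 0.40 ± 0.37 for Cxcl14 and -0.17 ± 0.33 for Cxcl16, and those of Ccl27a and Cxcl16 changed sign once trends on GC content and gene length were removed (-0.31 and 0.19). The smallest p-values in the list belonged to Cxcl9, with a log2 fold change of -2.41 ± 1.15, and Cxcl12, with -1.62 ± 0.88, neither past the threshold (adjusted p = 0.412 and 0.449). As a set the chemokine genes had a median log2 fold change of -0.40 and were not called (camera, adjusted p = 0.305). That median depended on the libraries and the tool: it was -0.044 without control 15, -1.09 without suppressed mouse 18, -0.14 without suppressed mouse 68, -0.79 with voom and 0.027 with quality-weighted voom.

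Across the transcriptome, no gene passed an adjusted p of 0.05 among 12090 tested genes (edgeR quasi-likelihood test, smallest adjusted p 0.377). At an unadjusted p under 0.05 there were 1528 genes, 1079 higher and 449 lower in suppressed mice. That number was 815, 355 and 351 without control 15, 22 or 23, and 3010 and 2565 without suppressed mouse 68 or 69. The same comparison gave 231 genes with DESeq2, 28 with limma voom with sample quality weights and 0 with plain limma voom. The groups did not overlap in 4322 genes, 1874 higher and 2448 lower in suppressed mice, or 35.8% of those tested. Chance gives 10% for independent libraries, and other splits of these 6 libraries, in which controls 22 and 23 were nearly identical, gave up to 14.6%. In simulated counts with the observed spread, the quasi-likelihood test recovered 4% of genes changed 4-fold and 52% of genes changed 16-fold with 0 false calls, and DESeq2 made 62 false calls among 164. Adjusted over the list alone in edgeR, members passed in 6 of the fixed lists (suprabasal, Langerhans, fibroblast, Wnt, alarmin and glucocorticoid), and in each of the other lists that number was 0. This adjustment ran within each list with no control across lists, so some of these passes can arise by chance. Over all genes edgeR called 0 members of any list, whereas DESeq2 called members of many lists, among them 7 suprabasal genes, 2 Langerhans genes and 1 glucocorticoid target. Of the genes named below, DESeq2 also called Wnt6, Wnt4, Il36b, Gbp7, Cd86, Nfkbiz, Krt35, Dbp, Uqcrc1, Rps14, Plaur and Sparc.

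Among genes with a mean of at least 5 CPM whose groups did not overlap, the 4 of smallest p in each direction are given as values, since none passed the threshold (adjusted p = 0.377 for each). Tsc22d3, a glucocorticoid-induced transcriptional regulator on chromosome X from 140539528 to 140600659 (mm10, minus strand), had 433 ± 13.8 CPM in controls and 130 ± 20 CPM in suppressed mice, a log2 fold change of -1.74 ± 0.32. H2-Aa, an MHC class II chain on chromosome 17 from 34282744 to 34287823, had 36.4 ± 18.1 and 5.13 ± 1.22 CPM. Bpifc, on chromosome 10 from 85959340 to 86011895, had 39.1 ± 3.50 and 7.20 ± 2.60 CPM. Lce1a2, a cornified envelope gene on chromosome 3 from 92668613 to 92670315, had 12.4 ± 3.85 and 0.848 ± 0.376 CPM; it belongs to a family of near-identical genes, so its counts are uncertain. In the other direction, Wnt6, a Wnt ligand on chromosome 1 from 74771892 to 74785322, had 2.57 ± 0.762 CPM in controls and 23.6 ± 12.5 CPM in suppressed mice. Slc4a8, a bicarbonate transporter on chromosome 15 from 100761747 to 100823968, had 3.71 ± 1.80 and 25.5 ± 8.27 CPM. Ppp1r35, on chromosome 5 from 137778849 to 137780110, had 10.1 ± 1.78 and 43.1 ± 11.8 CPM, and the noncoding transcript AA465934, on chromosome 11 from 83291699 to 83294632, had 0.981 ± 0.379 and 25.8 ± 20.9 CPM. DESeq2 called all 8 of these genes, and the quality-weighted voom fit called Tsc22d3, Slc4a8, Ppp1r35 and AA465934.

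**Figure D1:**
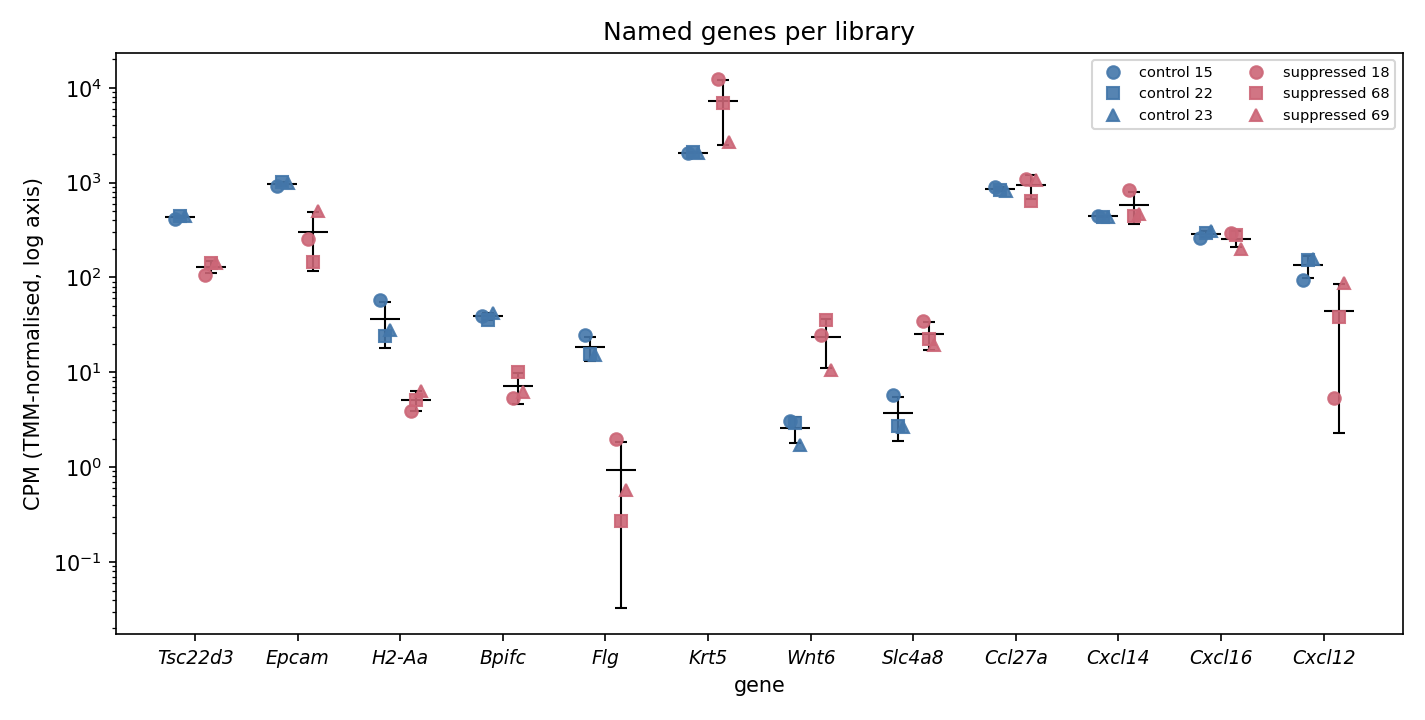
TMM-normalised CPM on a log axis for 12 named genes. Each point is a library (blue, control mice; red, suppressed mice), and each bar shows the mean and SD of 3 mice. Tsc22d3 stood at 107 to 142 CPM in suppressed libraries and at 418 to 443 CPM in controls, whereas the suppressed and control values of Ccl27a, Cxcl14 and Cxcl16 overlapped.

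Genes of the upper epidermal layers lay lower in suppressed mice as a set. Of 29 tested suprabasal and cornification genes, 24 had a log2 fold change below 0 and 14 were lower in every suppressed library than in every control, with 1 higher. The median log2 fold change was -1.48, and the list was called by camera (adjusted p = 2.05e-07). With an estimated correlation it was not called (adjusted p = 0.0905), and fry gave 0.00564. The estimated correlation was -0.0054, below the preset 0.01, so a larger correlation among its genes was not why the call was lost. Among genes with a mean of at least 5 CPM the median was -0.74, and with quality-weighted voom it was -2.28. In other splits of the 6 libraries, camera with the preset correlation called 6 to 12 lists, against 8 in the real split. In those splits the camera adjusted p of the suprabasal list was as low as 0.0056. The mean of log2(CPM + 1) over the list was 6.17, 6.39 and 6.37 in controls 15, 22 and 23, and 4.67, 4.55 and 5.05 in suppressed mice 18, 68 and 69. In edgeR no member passed over all genes, while 6 were lower when adjusted over the list alone, and DESeq2 called 7 members over all genes. Flg, which encodes filaggrin of the keratin matrix, had 18.4 ± 5.26 CPM in controls and 0.938 ± 0.905 CPM in suppressed mice. Lce1b, also in the near-identical family, was at 0 in all suppressed libraries, at least 9.09-fold lower against the mean floor of 3 counts per library. The other members, named after their values were seen, were Ivl (involucrin, 284 ± 10.2 and 38.6 ± 32.2 CPM), Grhl3, Lce1m and Flg2. Early suprabasal keratins overlapped between the groups, with log2 fold changes of -0.62 ± 0.76 for Krt10 and 0.57 ± 0.88 for Krt1.

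Langerhans and dendritic cell markers also lay lower as a set. Of 11 tested markers 9 were lower in every suppressed library, with a median log2 fold change of -1.98. Camera called the list (adjusted p = 9.62e-07, and 0.659 with an estimated correlation). The adjustment gave this same 0.659 to several lists. Their unadjusted camera p with an estimated correlation ran from 0.0451 for the Langerhans list to 0.308 for T-cell retention factors. In other splits of the 6 libraries the camera adjusted p of this list was as low as 3.22e-05. Epcam, which follicular keratinocytes also express, had 976 ± 45.5 CPM in controls and 301 ± 185 CPM in suppressed mice, and Mfge8 had 48.8 ± 25.2 and 83.5 ± 74.1 CPM. Adjusted over the list alone, 6 markers were lower: H2-Aa, Cd207, H2-Eb1, Epcam, Cd74 and Ctss. Cd207 (langerin), named after its values were seen, stood at 15.8, 7.55 and 6.36 CPM in controls 15, 22 and 23, and at 0.303, 0 and 0 CPM in suppressed mice 18, 68 and 69.

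**Figure D2:**
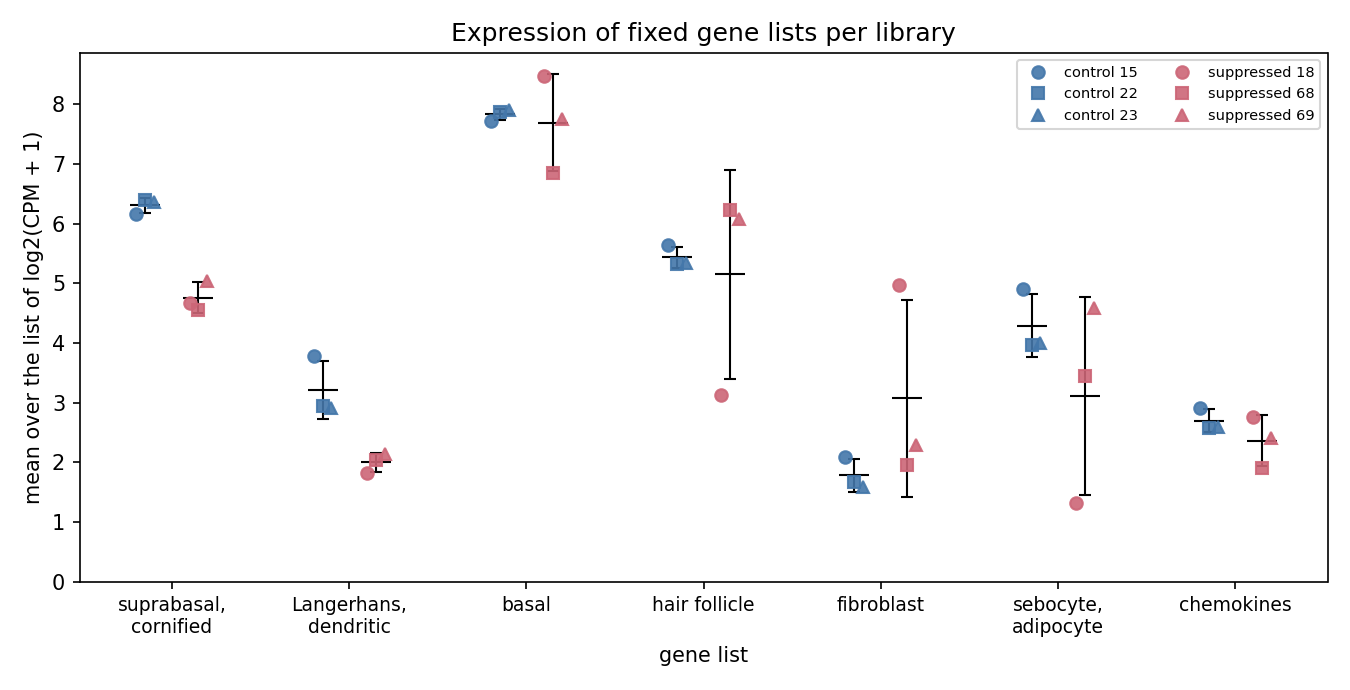
Mean of log2(CPM + 1) over the detected genes of 7 lists, per library (blue, control mice; red, suppressed mice), with bars for the mean and SD of 3 mice. The suprabasal list separated the groups (4.55 to 5.05 against 6.17 to 6.39), and in the hair follicle and fibroblast lists suppressed mouse 18 stood apart, at 3.13 and 4.97.

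Basal keratinocyte genes were not called as a set (camera, adjusted p = 0.391), and 15 of 25 had a log2 fold change above 0. Krt5, a basal keratin, had 2070 ± 5.18 CPM in controls and 7265 ± 4774 CPM in suppressed mice, Krt14 had 8661 ± 634 and 24740 ± 15320 CPM, and Itga3 had 48.0 ± 6.42 and 173 ± 95.1 CPM; none passed the threshold. Hair follicle genes were not called either (adjusted p = 0.886). Their median log2 fold change was 0.10 and the direction was up in camera and down in fry. Krt35 and Lgr6 had log2 fold changes of 3.44 ± 0.99 and 1.01 ± 0.43. Without suppressed mouse 18 the follicle list was called up, with a median of 0.65 (adjusted p = 0.00279). This call used the preset correlation. With an estimated correlation over all 6 mice the camera adjusted p was 0.986. The follicle median turned to -0.34 without suppressed mouse 68, -0.61 with voom and -1.41 with quality-weighted voom. The follicle list stood at 3.13 in suppressed mouse 18, against 5.32 to 5.64 in controls and 6.24 and 6.09 in suppressed mice 68 and 69. Wound-associated keratinocyte genes were not called (adjusted p = 0.391), with -0.91 ± 0.39 for Sprr1a and 3.93 ± 1.92 for Stfa1. The latter, a member of a multigene family, turned to -0.52 without suppressed mouse 18. The wound list was called down without suppressed mouse 18 (adjusted p = 0.0421, median -0.56) and with GC content and gene length offsets (0.00729). With an estimated correlation over all 6 mice its camera adjusted p was 0.659. Without suppressed mice 18 and 68 together, which leaves 1 suppressed mouse, the wound median was -0.67.

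Several housekeeping lists were called up in suppressed mice by camera, although the list levels of the ribosomal and oxidative phosphorylation genes overlapped between the groups. Of 54 cytosolic ribosomal protein genes 53 had a log2 fold change above 0, with a median of 0.81 (camera, adjusted p = 1.90e-09; 0.659 with an estimated correlation), and Rps14 had 1173 ± 132 CPM in controls and 3107 ± 921 CPM in suppressed mice, with Rps15 at 384 ± 83.4 and 1044 ± 306 CPM. The ribosomal median was 0.47 without suppressed mouse 18 (adjusted p = 0.00227). The mean of log2(CPM + 1) over the ribosomal list was 9.12, 8.78 and 8.72 in controls 15, 22 and 23, and 10.17, 8.91 and 9.49 in suppressed mice 18, 68 and 69 (exact permutation p = 0.2). Counts of ribosomal protein genes can be shared with processed pseudogenes. Nuclear-encoded oxidative phosphorylation genes had a median of 0.68 over 46 genes (adjusted p = 9.72e-07; 0.659 with an estimated correlation), with Uqcrc1 at 606 ± 99.9 and 2226 ± 1026 CPM and Ndufs8 at 151 ± 50.8 and 378 ± 87.8 CPM. The level of this list was 8.02, 7.53 and 7.52 in controls 15, 22 and 23, and 8.48, 8.004 and 8.18 in suppressed mice 18, 68 and 69 (exact permutation p = 0.2). All 20 glycolysis genes had a fold change above 0, with a median of 0.93 (adjusted p = 0.000245; 0.659 with an estimated correlation), with Tpi1 at 309 ± 66.9 and 681 ± 348 CPM and Pkm at 664 ± 88.1 and 1343 ± 567 CPM. The glycolysis level was 6.16 to 6.48 in controls and 6.53 to 7.33 in suppressed mice (exact permutation p = 0.1). Without suppressed mice 18 and 68 together, which leaves 1 suppressed mouse, the glycolysis median fell to 0.22. The glycolysis median was 0.58 without suppressed mouse 68.

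Cell cycle genes had a median log2 fold change of 0.64 over 37 genes (camera, adjusted p = 0.0113; 0.708 with an estimated correlation), with Cdc20 at 28.8 ± 15.04 CPM in controls and 106 ± 45.0 CPM in suppressed mice and Cdca8 at 10.3 ± 4.46 and 33.7 ± 11.8 CPM. This call was lost without control 22 (0.0668), control 23 (0.0814) or suppressed mouse 18 (0.172), and with controls 22 and 23 summed (0.0719). Without suppressed mice 18 and 68 together, which leaves 1 suppressed mouse, the cell cycle median was 0.44. The cell cycle median ranged from 0.29 without suppressed mouse 18 and 0.41 without control 23 to 1.16 without control 15, and was 1.05 with GC content and gene length offsets. The cell cycle level of 4.65 in control 15 lay within the 3.90 to 4.75 of suppressed mice (exact permutation p = 0.3). Wnt pathway genes had a median of 0.72 over 22 genes (adjusted p = 0.0251; 0.659 with an estimated correlation), and Wnt6 was higher when adjusted over the list alone. Wnt4 had 43.1 ± 6.08 and 151 ± 81.3 CPM. The Wnt call was lost without control 15 (0.140), without suppressed mouse 68 (0.161) or with GC content and gene length offsets (0.191). The Wnt median was 1.09 without suppressed mouse 18, 0.45 without suppressed mouse 69, 0.37 with the offsets, 0.26 with voom and 0.028 with quality-weighted voom. The Wnt level of 3.38 in suppressed mouse 18 lay within the 3.10 to 3.44 of controls (exact permutation p = 0.3).

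Immune and inflammatory lists were not called by camera under the first-choice settings (6 separate mice, TMM, the count filter and no offsets), but the alarmin and interferon lists were called in other settings. Alarmin and epithelial cytokine genes had a camera adjusted p of 0.123, and 1 member was lower when adjusted over the list alone: Il36b, an interleukin 36 cytokine on chromosome 2 from 24153161 to 24160519, had 6.38 ± 0.419 CPM in controls and was at 0 in all suppressed libraries, at least 17.3-fold lower against the mean floor. Il36rn, the interleukin 36 receptor antagonist, had 67.7 ± 9.70 and 18.2 ± 13.1 CPM. The alarmin list was called down without suppressed mouse 18 (adjusted p = 7.83e-05, median -1.61 against -0.10) and with no low-count filter (0.0201). These calls used the preset correlation, and with an estimated one over all 6 mice the camera adjusted p was 0.761. Without suppressed mice 18 and 68 together, which leaves 1 suppressed mouse, the alarmin median was -0.95. Interferon-stimulated genes had an adjusted p of 0.119, with Gbp7 at 2.07 ± 1.25 CPM in controls and 0 in all suppressed libraries, and Socs1 at 11.6 ± 1.96 and 36.8 ± 15.5 CPM. Against the mean floor, the fall of Gbp7 was bounded only at 5.63-fold or more. The interferon list was called down without suppressed mouse 18 (adjusted p = 0.0183), without control 23 (0.0257) and with controls 22 and 23 summed (0.0459). It was also called down with GC content and gene length offsets (0.00803) and with no low-count filter (0.00774). With an estimated correlation over all 6 mice the interferon list had a camera adjusted p of 0.761. MHC class I genes had an adjusted p of 0.692, with log2 fold changes of 1.07 ± 0.35 for Psme1 and -1.31 ± 0.48 for Erap1, the latter turning to 0.17 with GC content and gene length offsets. Factors of epidermal T-cell retention and survival had an adjusted p of 0.239, with Cd86 at 1.41 ± 0.354 CPM in controls and 0 in all suppressed libraries, and Tnfsf9 at 6.21 ± 3.62 and 21.1 ± 16.9 CPM. Against the mean floor, the fall of Cd86 was bounded only at 3.83-fold or more. NF-kappaB targets had an adjusted p of 0.987, with a median of 0.07 against a direction of down in camera, and contained Nfkbiz at 168 ± 3.34 and 62.5 ± 18.04 CPM and Nfkb2 at 37.2 ± 2.08 and 75.1 ± 25.2 CPM.

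Genes linked to adrenergic signalling were not called. The adrenergic receptor and signalling list had a camera adjusted p of 0.987 and a median of 0.05, with opposite directions in camera and fry, and Gnai2 and Adcy3 had log2 fold changes of 1.01 ± 0.41 and 1.29 ± 0.58. Adrb1 had 0.300 ± 0.169 CPM in controls and 0.555 ± 0.962 CPM in suppressed mice. Dbh was at 0 in every library and Chrm4 was at or below 0.165 CPM; as the driver acts in neurons, which were not sorted, these values do not check the labels. The cAMP and CREB target list had an adjusted p of 0.277, with log2 fold changes of -2.51 ± 0.81 for Ppargc1a and -1.20 ± 0.55 for Nr4a2. Glucocorticoid targets had an adjusted p of 0.391, and in this list Tsc22d3 was lower when adjusted over the list alone, while Zbtb16 had 33.0 ± 9.57 and 11.4 ± 4.38 CPM.

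Of the remaining pathway lists none was called by camera under the first-choice settings. Cholesterol synthesis was called down without suppressed mouse 68 (adjusted p = 0.00667, median -0.48). With an estimated correlation over all 6 mice its camera adjusted p was 0.659. Without suppressed mice 18 and 68 together the cholesterol median was -0.30. That fit leaves 1 suppressed mouse, so its calls of the cholesterol and unfolded protein lists are not weighed. Under the first-choice settings the adjusted p was 0.636 for immediate-early and dissociation stress genes, whose median of -0.06 differed in sign from the mean of 0.08 and the direction of up in camera (Ier2 at 1.21 ± 0.33 and Jund at 2.203 ± 0.63 on the log2 scale). It was 0.391 for circadian clock genes (Dbp 2.66 ± 0.76) and 0.818 for hypoxia genes, whose mean of 0.21 differed in sign from the median of -0.12 and the direction of down in camera (Ndufa4l2 4.92 ± 1.54, Ddit4 -0.85 ± 0.44). Suppressed mouse 18 carried the value of Ndufa4l2, which was 1.34 without it. The adjusted p was 0.272 for cholesterol synthesis (Sqle -1.24 ± 0.41, Ebp 1.01 ± 0.38), 0.859 for the unfolded protein response (Sesn2 1.52 ± 0.59, Asns 0.86 ± 0.38) and 0.266 for matrix and basement membrane genes (Plaur 1.42 ± 0.37, Hspg2 2.85 ± 1.02). Suppressed mouse 68 carried the value of Hspg2, which was 0.91 without it. The adjusted p was 0.583 for TGF-beta and BMP targets (Id4 -1.15 ± 0.64, Tgfbi 0.85 ± 0.49), where Id4 turned to 0.71 with GC content and gene length offsets and Tgfbi was 0.20 without suppressed mouse 18.

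Markers of other cell types were uneven between libraries. Fibroblast markers had a median log2 fold change of 2.68 over 9 genes (camera, adjusted p = 0.000459; 0.659 with an estimated correlation), and the call was lost without suppressed mouse 18 (0.137), where the median was 0.61. Adjusted over the list alone 3 were higher, Sparc and, named after their values were seen, Col5a1 and Col6a2. Col1a1 stood at 565 CPM in suppressed mouse 18 and between 2.01 and 12.1 CPM in the other libraries, and Sparc stood at 726 CPM in suppressed mouse 18, 117 CPM in both other suppressed mice and 40.3 to 57.4 CPM in controls. Sebocyte and adipocyte markers were not called (adjusted p = 0.124), with Scd1 at 701 ± 405 CPM in controls and 338 ± 480 CPM in suppressed mice and Mgst1 at 511 ± 374 and 406 ± 567 CPM. The sebocyte list was called down without control 22 (adjusted p = 0.0313), control 23 (0.0268) or suppressed mouse 69 (0.000765, median -2.68 against -0.65), and with controls 22 and 23 summed (0.0320). Its median was -0.061 without control 15, -0.091 without suppressed mouse 18, and 0.34 without suppressed mice 18 and 68. Melanocyte markers were not called (adjusted p = 0.886; median 0.37, direction of down in camera), with Dct at 33.2 ± 35.5 and 29.9 ± 28.8 CPM and Pmel at 9.89 ± 11.9 and 27.6 ± 24.9 CPM. The melanocyte median was 1.36 without control 15, -0.43 without control 22 and -1.23 without suppressed mouse 69. Erythroid markers were not called (adjusted p = 0.583), with Hba-a1 at 10.9 ± 10.4 and 59.7 ± 53.1 CPM and Hbb-bs at 10.1 ± 9.30 and 33.7 ± 34.6 CPM. They were called up without suppressed mouse 69 (adjusted p = 0.00989, median 2.33) and down without suppressed mice 18 and 68 (0.00437, median -4.53).

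The other marker lists had fewer than 5 tested genes and are given as values. Their means of log2(CPM + 1) in controls and suppressed mice were 0.766 ± 0.0158 and 0.861 ± 0.224 for T cells, 0.871 ± 0.0674 and 0.569 ± 0.288 for neutrophils and macrophages, and 0.816 ± 0.0461 and 0.810 ± 0.224 for Merkel cells. They were 0.655 ± 0.221 and 0.773 ± 0.135 for endothelial and mural cells, 0.452 ± 0.0628 and 0.527 ± 0.129 for skeletal muscle, and 0.894 ± 0.0715 and 0.813 ± 0.254 for neurons and Schwann cells. For T cells, Trbc2 had 48.1 ± 5.20 CPM in controls and 36.6 ± 3.67 CPM in suppressed mice, and Thy1 had 1.97 ± 1.12 and 8.66 ± 13.1 CPM. Suppressed mouse 18, the library with high fibroblast markers, carried the Thy1 mean. Thy1 stood at 23.8 CPM there and at 0.803 and 1.41 CPM in suppressed mice 68 and 69. Cd68 and S100a8, of macrophages and neutrophils, had 4.69 ± 2.10 and 5.78 ± 2.47 CPM in controls and 3.20 ± 1.99 and 1.22 ± 1.84 CPM in suppressed mice. Krt8 and Krt18, of Merkel cells, had 12.0 ± 3.85 and 7.25 ± 1.27 CPM in controls and 10.9 ± 8.49 and 9.71 ± 6.28 CPM in suppressed mice. Cspg4 and Acta2, of mural cells, had 19.7 ± 7.35 and 5.59 ± 5.12 CPM in controls and 44.3 ± 52.1 and 4.88 ± 3.07 CPM in suppressed mice. Mylpf and Ckm, of skeletal muscle, had 7.03 ± 1.38 and 0.212 ± 0.258 CPM in controls and 7.87 ± 1.18 and 0.202 ± 0.350 CPM in suppressed mice. Mbp and Slc6a2, of Schwann cells and neurons, had 20 ± 3.50 and 2.48 ± 0.189 CPM in controls and 22.7 ± 25.1 and 6.37 ± 10.5 CPM in suppressed mice. Suppressed mouse 18 carried both suppressed means, with Mbp at 51.6 CPM and Slc6a2 at 18.5 CPM. In suppressed mice 68 and 69, Mbp stood at 9.10 and 7.45 CPM and Slc6a2 at 0.134 and 0.497 CPM.

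Suppressed mice 18 and 68 stood apart from the other libraries. The first principal component, with 68.3% of the variance, separated suppressed mouse 68, and the second, with 22.3%, separated suppressed mouse 18. Suppressed mouse 68 had 12094 detected genes against 14892 to 16185 elsewhere, and 106 of 6299 genes with a mean of at least 20 CPM were at 0 there. Its count-weighted GC content was 54.3%, against 49.9% to 51.1% elsewhere. Controls 22 and 23 had a coefficient of variation of 0.04996 between them, against 0.284 for the next closest pair. Their counts differed by more than sampling noise (chi-square per gene 3.10), as separate libraries of 1 RNA sample also would. They were counted as 2 samples because the labels name separate mice, and with both summed 358 genes had an unadjusted p under 0.05. Mitochondrially encoded genes were listed at 0 in every library. Of the sex-linked genes, Xist was listed at 0 in every library, Ddx3y had 0 counts in suppressed mouse 68 and 898 to 2093 counts elsewhere, and Kdm5d had 38 to 171 counts in all libraries. Suppressed mouse 68 also had 0 counts of Eif2s3y (740 to 1293 elsewhere) and 4 of Uty (105 to 429 elsewhere). Low counts in that library were not confined to chromosome Y, with 105 counts of the X homologue Ddx3x (1339 to 4032 elsewhere) and 6 of Eif2s3x (266 to 660 elsewhere).

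**Figure D3:**
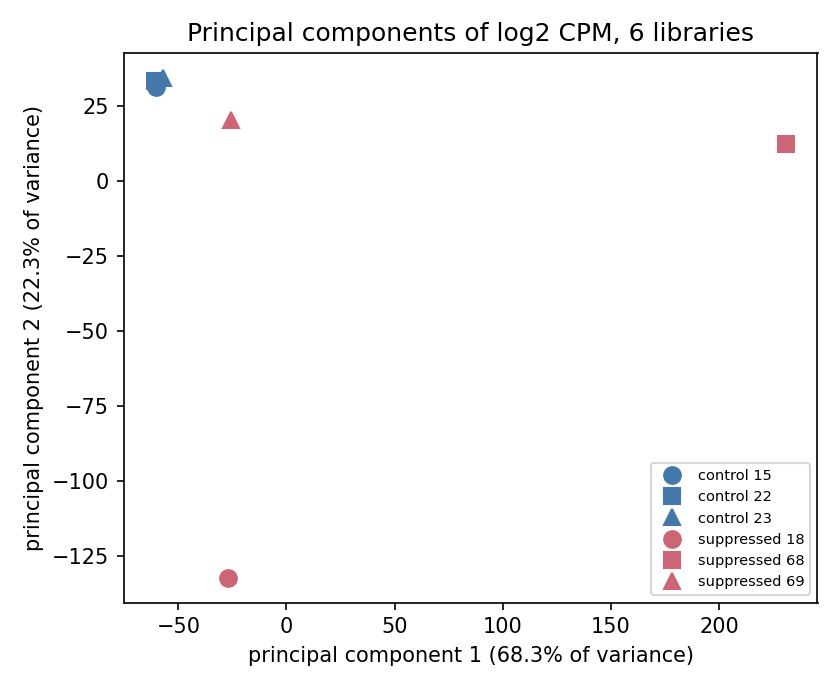
Principal components of log2 CPM for the 6 libraries (blue, control mice; red, suppressed mice), with the share of variance on each axis. Suppressed mouse 68 lies at 231 on the first component and suppressed mouse 18 at -132 on the second, while suppressed mouse 69 lies near the controls.

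The group means of library measures were compared with an exact two-sided permutation test, for which 3 against 3 mice allow no p below 0.1. Genes detected were 15200 ± 244 in controls and 14390 ± 2091 in suppressed mice (exact permutation p = 0.7), and the 50 most abundant genes took 22.2 ± 0.343% and 27.8 ± 6.16% of counts (exact permutation p = 0.3). Lars2 took 0.195 ± 0.0701% of counts in controls and 1.72 ± 2.06% in suppressed mice (exact permutation p = 0.1). Each of the 3 suppressed libraries lay above every control, at 0.4955%, 4.099% and 0.5685% in mice 18, 68 and 69. Suppressed mouse 68 carried most of the suppressed mean. Count-weighted GC content was 50.1 ± 0.145% and 52.1 ± 1.93%, and count-weighted gene length 4137 ± 78.5 and 3703 ± 210 bases (exact permutation p = 0.1 for each).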

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

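Summing controls 22 and 23, leaving out suppressed mice 18 and 68 together, and the GC content and gene length offsets were chosen after seeing the data. No paired analysis was possible because the groups share no mouse numbers. The count of changed genes was 0 in every edgeR setting and in limma voom, but 231 with DESeq2 (118 higher, 113 lower) and 28 with sample quality weights (16 higher, 12 lower), with 21 genes shared; the cause was not tested. DESeq2 made 62 false calls among 164 on simulated counts. The smallest adjusted p of the edgeR settings ranged from 0.0802 (suppressed 18 and 68 left out) to 0.849 (without control 22). Genes at an unadjusted p under 0.05 numbered 1528, and 355 and 351 without control 22 or 23, 358 with both summed, 815 without control 15, 3010 and 2565 without suppressed 68 or 69, and 3651 without suppressed 18 and 68. Leaving out suppressed mice 18 and 68 leaves a lone sample, which is assumed to vary like the controls. Chemokine genes called numbered 0 in every setting run. The edgeR settings and plain limma voom called 0 genes of any kind, so their 0 adds nothing. Only DESeq2 and the quality-weighted fit could have called a chemokine gene, and neither did.

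Camera called 8 lists, 0 with an estimated correlation and 1 (suprabasal) with fry. Leaving out 1 mouse gave 7 to 10 lists. The suprabasal, Langerhans, ribosomal and oxidative phosphorylation lists kept their direction and call in every other setting with the preset correlation, with adjusted p up to 2.93e-05, 0.000829, 0.00227 and 0.00154. The offsets moved the median log2 fold change of all genes from -0.03 to 0.22 (0.12 with no filter, -0.29 with voom, -0.14 with quality weights), and that of the suprabasal list from -1.48 to -1.22; it was -0.74 with a mean of at least 5 CPM, where low genes are left out, and -2.28 with quality weights. Among lists not called under the first-choice settings, alarmin, interferon, hair follicle, wound, cholesterol, unfolded protein, sebocyte and erythroid lists were called in at least 1 other setting. These calls all used the preset correlation, and some came from the fit that leaves 1 suppressed mouse. The medians of the 8 called lists and of the cholesterol, matrix and interferon lists kept their sign in every setting, and that of every other tested list turned sign in at least 1. Leaving out mitochondrially encoded genes changed nothing, since all were at 0.

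Fold changes of genes that missed the threshold turned sign as follows; the cause was not tested. With voom, Cspg4 was -0.14, Mbp -0.50 and Slc6a2 -1.15. With quality weights, Acta2 was 0.089, Cd68 0.16, Cspg4 -1.45, Dct 0.55, Mbp -0.30, Mfge8 -0.049 and Slc6a2 -0.041. Without suppressed 18 and 68, Dct was 0.89, Hba-a1 -3.56, Hbb-bs -3.74, Mbp -1.44, Mgst1 1.04, Mylpf -0.094, Scd1 0.34, Slc6a2 -2.31 and Thy1 -0.52. With the offsets, Acta2 was 0.31, Ccl27a -0.31, Cxcl16 0.19, Dct 1.84, Erap1 0.17, Id4 0.71, Krt18 -0.20, Mgst1 0.13 and Mylpf -0.070. Leaving out 1 mouse gave ranges of -0.69 to 0.86 for Acta2, -0.35 to 1.72 for Cspg4, -1.23 to 1.22 for Dct, -0.0196 to 0.85 for Krt18, -0.93 to 0.26 for Krt8, -1.29 to 0.62 for Mbp, -0.10 to 1.27 for Mfge8, -2.68 to 0.45 for Mgst1, -2.88 to 1.92 for Slc6a2, -0.52 to 4.50 for Stfa1 and -0.84 to 2.65 for Thy1. Of the other values of named genes, 1230 kept their sign and side of the threshold and 26 kept their sign and passed it.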

Other observations

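The tests below were chosen after the results were seen, except the splits of the 6 libraries for genes and lists called. Several were also revised after their values were seen. The rule for glucocorticoid targets was changed to use the spread of the members, which moved the result from excluded to undecided. A single aberrant library as the source of the late-differentiation pattern, and fewer reads or low library complexity in suppressed 68, were tested first and are no longer weighed. Dilution was first tested on the groups' median and then in each library, which left it open in suppressed 68. The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split called 0 genes and the highest of the others 0, so all 10 gave as many. It called 8 lists and the highest of the others 12, with 6 splits giving as many. It gave 1528 genes at an unadjusted p under 0.05 and the highest of the others 335, with 1 split, the real one, giving as many.

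Lower late-differentiation genes in suppressed mice are a hypothesis that these tests bear on. GC content or gene length bias as the whole cause is argued against by the median log2 fold change of the suprabasal list. It was -1.22 with the offsets and -1.48 without them. The list also kept its camera call with the offsets (adjusted p = 2.679e-14 at the preset correlation). That call decides little by itself. Without offsets the list was not called with an estimated correlation (camera, adjusted p = 0.0905), and other splits of the libraries gave values as low as 0.0056. That estimated correlation was -0.0054, so correlated genes were not why the call was lost. A loss of suprabasal cells of every stage as the whole cause was weighed with the early genes Krt1, Krt10, Krt77, Krtdap, Sbsn and Dmkn. They lay above the late genes, the 23 other tested members of the list, by at least 0.8009 log2 units in each suppressed library. This was more than the SD of the 6 early genes there, which is a spread between genes and not between mice. Such a loss would leave no gap only if the remaining cells expressed no early genes, which was not tested. The gap therefore cannot exclude that loss. The gap was not separated from abundance, as the list median was -0.74 among genes with a mean of at least 5 CPM. The early medians were themselves -0.72 in suppressed 68 and -0.74 in suppressed 69 (0.51 in 18), so a part of the change may go with such a loss. Dilution of all keratinocyte RNA by other cells would lower basal genes by about as much, and is argued against in suppressed 18 and 69, where the basal medians of 0.9599 and -0.1587 lay above the suprabasal ones by 3.05 and 1.14 (SD of basal genes 1.27 and 0.477), but not in suppressed 68, where the basal median was -1.133 and the gap 0.48 (SD 2.25). Dilution in suppressed 68 stays open, as does a loss of suprabasal cells of every stage. A sort that held fewer late-stage cells and suppression of sympathetic neurons itself also stay open, untested.

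Suppressed mice 18 and 68 may stand apart for different reasons. GC content and gene length explained 54.11% of the variance of the log2 ratio to controls in suppressed 68, consistent with such a bias as the larger part there, and 7.416% in suppressed 18, which argues against it there. In suppressed 18 the hair follicle list had a median log2 ratio of -2.655 while fibroblast markers had 3.95, consistent with a different mix of sorted cells; a sort for keratinocytes would be meant to remove fibroblasts. The follicle list was not low in suppressed 68 and 69, whose lower median was 0.5282. The median of suppressed 68 was not corrected for GC content and gene length, so the contrast rests mainly on suppressed 69. Such a contrast of single mice cannot exclude suppression of sympathetic neurons as the cause of the low follicle list. Thinned to the total of suppressed 68, the 4 deeper libraries detected at least 14702 genes, and suppressed 18 detected 14892 at its own lower total.

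Controls 22 and 23 may be 1 RNA or cDNA sample sequenced as 2 libraries: their coefficient of variation among low-count genes was 0.1302, against 0.423 for the next closest pair. Mice handled together remain a candidate explanation that was not tested.

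Lower Tsc22d3 and Zbtb16 could reflect lower glucocorticoid signalling in keratinocytes. The 16 other tested targets showed no shared fall, with a median log2 fold change of 0.2086, 8 above 0 and 8 below. Their SD of 1.09 is a spread between genes and not the error of that median. A test that uses this SD could hardly exclude the hypothesis, which therefore stays open.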
